A study of Homo sapiens with 6 samples.

How the data were processed

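RNA of single sorted cells was measured in 6 samples from 3 patients with multiple myeloma. Each patient gave clonal plasma cells from bone marrow (BM) and circulating tumor cells (CTC) from blood, so each group holds 3 samples and the samples of a patient share a replicate number. Per the labels, cells were sorted into the wells of plates and processed with the BD Precise assay, which copies RNA in each well with a well barcode and a molecular index. The deposited notes state that a sample was spread over plates of 96 wells, that each plate had its own lysis and library with its own sequencing index, and that reads were demultiplexed with bcl2fastq 2.19 at a minimum trimmed read length of 75 and a short adapter mask of 8. The values are molecular index counts per gene and well after the assay's own error correction, which the authors deposited as 1 joined table of whole-number counts. The aligner, the genome build and the annotation are not given in the sources used here. One library was sequenced again, per the deposited notes, and the second plate of CTC 2 was not analysed here.

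The table held 55765 rows and 960 wells from 10 plates, and 0 columns were left unmapped. Wells carry a plate code whose first letters (mo and sp) were read as abbreviations of bone marrow and peripheral blood and whose digit was read as the patient. The deposited notes do not spell these letters out, nor the letter x of 1 plate code, and every comparison between the groups rests on this reading. In the table used, BM 1, BM 2, BM 3 and CTC 3 had a pair of plates each, while CTC 1 and CTC 2 had 1 plate each. It did not hold the second plate of CTC 2. No plate held cells of more than 1 sample, so compartment and plate cannot be separated by the design. Y-linked genes and both genes of the X-inactivation center were removed before any step (421 rows, 0.0263% of counts). The 404 immunoglobulin rows stayed in the totals and are named only as a class, since they mark a clone. Of the remaining 55344 rows, 33515 carry a symbol of GENCODE 29. The rows without one hold 7.18% of the counts. Positions are those of GENCODE 29 on GRCh38 and were matched by symbol, as the authors' build is not known.

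A well counted as a cell when it had at least 200 detected genes, which kept 827 wells and left out 133. The kept wells held 2846431 counts. Counts of the kept wells were summed per sample and compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest), with the patient as a block and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Cells were not used as replicates in this comparison. The block leaves 2 residual degrees of freedom. The pairing comes from the labels, which name the patient, and deviations of same-numbered samples from their group means correlated at 0.580, 0.344 and 0.350 across genes. Without the block the count of genes past the threshold was 0.

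Gene lists were fixed before the data were examined. There were 20 lists of cell states and 11 of cell type markers, and the 18 lists with at least 5 tested genes were tested with limma 3.58.1 (camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry). Log2 values of counts scaled to an equal total (CPM) used a prior count of 2. The rule for named genes, fixed at the same time, takes up to 12 genes per direction with adjusted p under 0.05 and the same sign in the 3 pairs. Where fewer than 5 qualify, it takes the 5 with the lowest p and that sign pattern without calling them changed. From a fixed panel of 12 genes, 11 are reported whatever their test, as are 2 to 4 members of low p in each list.

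For values per cell, each cell was thinned at random to 2180 counts, the 25th percentile of the kept cells, and 620 cells had that depth. The cycling class holds cells with at least 2 detected genes among the 53 genes of the joined lists of DNA replication and of mitosis. Similarity is the mean Spearman correlation between cells of a sample over the 1746 genes detected in at least 10% of thinned cells. Mixing is the share of the 10 nearest neighbours with the same label, in 20 principal components with equal numbers of cells per label, divided by the share with no structure. Values per sample were compared by 2 exact permutation tests, both two-sided: the sign flips of the 3 pairs, whose smallest p is 0.25, and the reassignment of the 6 values, whose smallest p is 0.1. Both were adjusted over the 19 measures. Cells were sorted into single wells, so no doublet caller was run. Intervals for shares of cells are exact binomial at 95%, and cover counting error only. Python 3.11.15, scipy 1.17.1 and scikit-learn 1.9.0 were used.

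The tests were tried on simulated data. In simulated counts for 4249 genes, with 50 genes changed at each fold, the gene comparison recovered 2% of genes changed 2-fold, 24% at 4-fold, 76% at 8-fold and 80% at 16-fold, with 1 false call, and it made 0 calls where nothing was changed. The list comparison found a list shifted 2-fold (adjusted p = 1.64e-11 from camera) and called 0 other lists. In the measured data it also called lists when samples of a patient changed places between the groups. The simulated result therefore does not show how often lists are called in the measured data without a difference between the compartments. The mixing ratio was 1.02 for cells of the same simulated profile and 2.02 where 60 of 500 genes were shifted 4-fold. The 2.02 is the highest value the ratio can take with 60 cells per label. A comparison of plates found all 30 genes moved 30-fold in simulated plates and 0 others. Alternatives covered scaling, filters on genes and cells, other tools, the patient block, thinning, equal cell numbers and leaving out each patient. Added after seeing the data were the removal of wells rich in haemoglobin, the summing of gene copies that share a symbol, the use of 1 plate per sample, repeated thinning, the mitochondrial filter in the list test, and leaving out each patient in the comparison of patient with compartment.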

Results

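Single cells of 2 compartments were profiled in 3 patients with multiple myeloma, a cancer of clonal plasma cells. BM denotes the clonal plasma cells of the marrow and CTC the tumor cells in blood, with 3 samples each. The kept cells numbered 173 in BM 1, 156 in BM 2, 170 in BM 3, 92 in CTC 1, 82 in CTC 2 and 154 in CTC 3. Their summed counts were 605825, 628149 and 428433 in the BM samples and 519258, 173598 and 491168 in the CTC samples. CTC 2 was the shallowest of the 6 samples.

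The question behind the comparison was how circulating cells differ from the marrow cells of the same patient. Immunoglobulin transcripts made up 27.9% ± 13.7 (SD, n = 3) of counts in BM and 33.1% ± 5.03 (n = 3) in CTC samples. Mitochondrial transcripts took 16.3% ± 7.62 in BM and 11.8% ± 2.27 in CTC samples, with BM 1 at 25.1% and the other 5 samples between 9.19% and 13.2%. Ribosomal protein genes held 10.6% ± 1.35 of counts in BM and 9.15% ± 3.02 in CTC samples. The 10 most abundant genes held 2.79 ± 1.90 percentage points more of the counts in CTC samples, in the same direction in 3 of 3 patients. The median cell had 3105 ± 644 counts in BM and 3512 ± 1867 in CTC samples, and 1028 ± 142 against 1108 ± 450 detected genes. None of these differences passed the exact sign-flip permutation test, which gave p = 0.25 for the 10 most abundant genes, the smallest p it can give, p = 0.5 for the immunoglobulin, mitochondrial and ribosomal shares, and p = 0.75 for both depths. Every value was 1 after adjustment.

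MT-ND6, a subunit of respiratory complex I encoded on the mitochondrial genome, was the single gene that passed the test. Its level, in counts scaled to an equal total per sample (CPM), was 41.3, 63.7 and 39.7 in the BM samples and 578, 1596 and 401 in the CTC samples of patients 1, 2 and 3. The log2 fold change was 3.92 (3.80 ± 0.52 SD over 3 pairs), with adjusted p = 0.0479 from edgeR's quasi-likelihood test. The gene lies on chromosome M of GRCh38 from position 14149 to 14673, on the minus strand, opposite to most other mitochondrial genes, and whether the counting used the strand is not given in the sources used here. The plates of CTC 3 differed in it: the first held 79.9 CPM and the second 735, while the 6 BM plates ranged from 31.1 to 77.9. A count of MT-ND6 was found in 18 of 73 cells on the first CTC 3 plate and in 66 of 81 on the second.

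Of 4249 genes tested, 1 was higher and 0 were lower in CTC samples at adjusted p under 0.05. At unadjusted p under 0.05, 43 were higher and 35 lower. These 78 genes are fewer than the share of 0.05 of tested genes that would be found with no difference at all. The sign was shared by the 3 patients in 19.3% of genes, where chance gives 25%. By edgeR the count was 0 without patient 1 (45 at unadjusted p under 0.05), 0 without patient 2 (77) and 38 without patient 3 (13 higher, 25 lower). It was also 0 without the patient block, where MT-ND6 had a log2 fold change of 4.09 and adjusted p = 0.916 from edgeR.

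The haemoglobin genes of red blood cells followed MT-ND6 in rank and did not pass the test. HBA2 (chromosome 16, 172876 to 173710) had a log2 fold change of 6.45, HBA1 (chromosome 16, 176680 to 177522) of 6.54 and HBB (chromosome 11, 5225464 to 5229395) of 5.86. Their adjusted p-values from edgeR were 0.507, 0.407 and 0.407. Without patient 3 they passed (edgeR adjusted p = 0.00451, 0.00201 and 0.0112), as they did with no filter on low counts (adjusted p up to 2.07e-06). HBB also passed with the DESeq2 test (adjusted p = 2.11e-08) and, by edgeR, with cells of other types removed (0.0394). HBA1 and HBA2 are nearly identical, and the split of counts between them is uncertain. The genes of the erythroid list that could be tested were these 3, and 3 of 3 passed when adjusted over the list alone. HBA2 stood at 2753 CPM in CTC 2 and 3076 in CTC 3, but at 19.3 in CTC 1, 79.6 in BM 2, 1.65 in BM 1 and 0 in BM 3. The counts came from few wells: 10 wells with at least 10 haemoglobin counts held 98.0% of them, and 9 of the 10 were CTC wells.

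**Figure D1:**
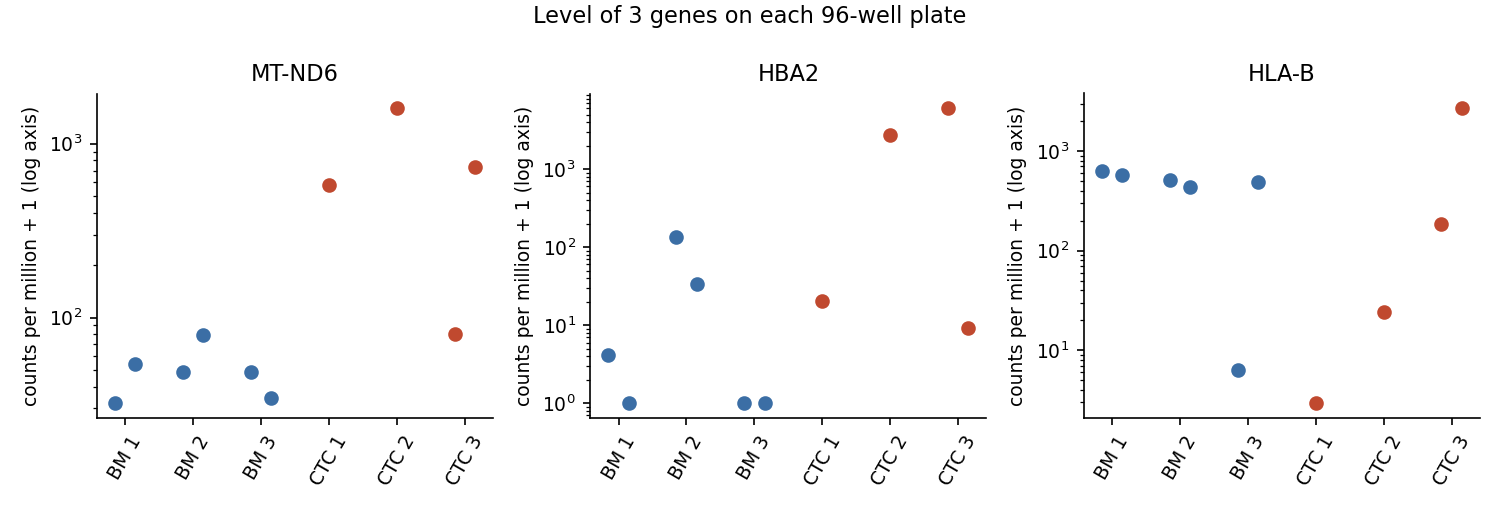
CPM plus 1, on a log axis, of MT-ND6, HBA2 and HLA-B on each plate, with BM samples in blue, CTC samples in red and each point 1 plate. MT-ND6 was 79.9 on 1 plate of CTC 3 and 735 on the other, HBA2 was 6028 and 8.30 on those plates, and HLA-B was 184 and 2690.

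ABCA8, a lipid transporter, completed the 5 genes of lowest p on the higher side, with a log2 fold change of 1.84 (pairs 1.55 ± 0.58 SD, n = 3). On the lower side were ID2, an inhibitor of basic helix-loop-helix transcription factors (−2.27), the RNA-binding protein gene HNRNPH3 (−2.40), HLA-C, a class I antigen-presenting molecule (−2.31), TIFA, an adaptor of NF-kappaB signaling (−1.89), and the ribosomal protein gene RPL23A (−2.82). Each of these 6 had adjusted p = 1.00 from edgeR and was not called changed. ID2 (chromosome 2, 8678845 to 8684453) went from 221, 172 and 60.7 CPM in BM to 17.3, 92.2 and 12.2 in CTC samples. TIFA (chromosome 4, 112274542 to 112285903) went from 42.9, 49.4 and 42.0 to 5.78, 23.0 and 12.2. HLA-C and RPL23A have close copies, so their counts are uncertain: HLA-C was at 84.5 and 372 CPM on the plates of BM 3 and at 19.97 and 295 on those of CTC 3, and RPL23A was at 1091 in BM 1 and at 49.4 or below in the other 5 samples. Without patient 3, HNRNPH3 (−3.28), HLA-C (−3.19) and RPL23A (−3.64) passed the test, with adjusted p between 0.0223 and 0.0264 from edgeR.

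No surface or migration gene of the fixed panel passed the test. SDC1, the plasma cell marker CD138, had a log2 fold change of −0.12, CD38 of 0.07 and TNFRSF17, the receptor BCMA, of 0.23. The homing receptor CXCR4 was at 0.24, the integrin gene ITGA4 at 0.68 and the adhesion receptor CD44 at −0.26. LGALS1 and VIM, genes with a role in cell motility, were at 0.14 and −0.58. The signs differed between patients for each of these 8 genes, and edgeR gave adjusted p = 1.00 for each. The spread over the 3 pairs was large, for example 1.17 (SD) for SDC1 and 0.92 for CXCR4 on the log2 scale. MKI67 (30 counts), CENPF (33) and VEGFA (57) had too few counts over the 6 samples to be tested.

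Cytosolic ribosomal protein genes were lower in CTC samples as a list. Of 76 tested members, 64 had a negative and 12 a positive log2 fold change, with a median of −0.26 and camera adjusted p = 1.45e-04 at the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.995) and with fry (adjusted p = 0.986), and also without patient 2 (adjusted p = 0.794) or patient 3 (0.219), at the preset correlation. RPL22 (−1.10), RPL36 (−0.60) and RPS27L (−0.67) had the lowest p after RPL23A. No member passed singly over all genes, and 0 passed when adjusted over the list alone by edgeR, with 1 at unadjusted p under 0.05. The summed level went up in patient 1, from 115905 to 122766 CPM, and down in patient 2, from 90399 to 62443, and patient 3, from 110619 to 89356.

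Class I antigen presentation genes and immediate early genes were lower as lists, though their summed counts had no common direction over the patients. Of 9 class I members, 8 were negative (median −0.35, camera adjusted p = 0.0314). The class I call was lost with an estimated correlation (adjusted p = 0.995), with fry (0.327) and, by camera, with thinned cells (0.0778) and without patient 1 (0.160). HLA-B was at −3.40, HLA-C at −2.31 and HLA-E at −0.67, and 0 members passed when adjusted over the list alone by edgeR (1 at unadjusted p under 0.05). HLA-B had no common direction: its pair values were −6.50, −4.33 and 2.50. The summed class I level was 5170, 6750 and 19354 CPM in BM and 3999.9, 7085 and 14356 in CTC samples.

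Of 17 immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus or of cell handling, 15 were negative (median −0.40, camera adjusted p = 0.0423). This call was lost with an estimated correlation (adjusted p = 0.995) and with fry (0.986), and by camera with no patient block (0.111), with thinned cells (0.357), with cells above 25% mitochondrial counts removed (0.08005), without wells rich in haemoglobin (0.0526) and without patient 3 (0.0648). The list turned to the higher side without patient 1 (0.895). IER2 was at −0.68, DUSP1 at −1.14 and EGR1 at −1.12. The summed level went down in patient 1, from 5102 to 2176 CPM, and up in patients 2, from 5078 to 6152, and 3, from 2166 to 2240.

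**Figure D2:**
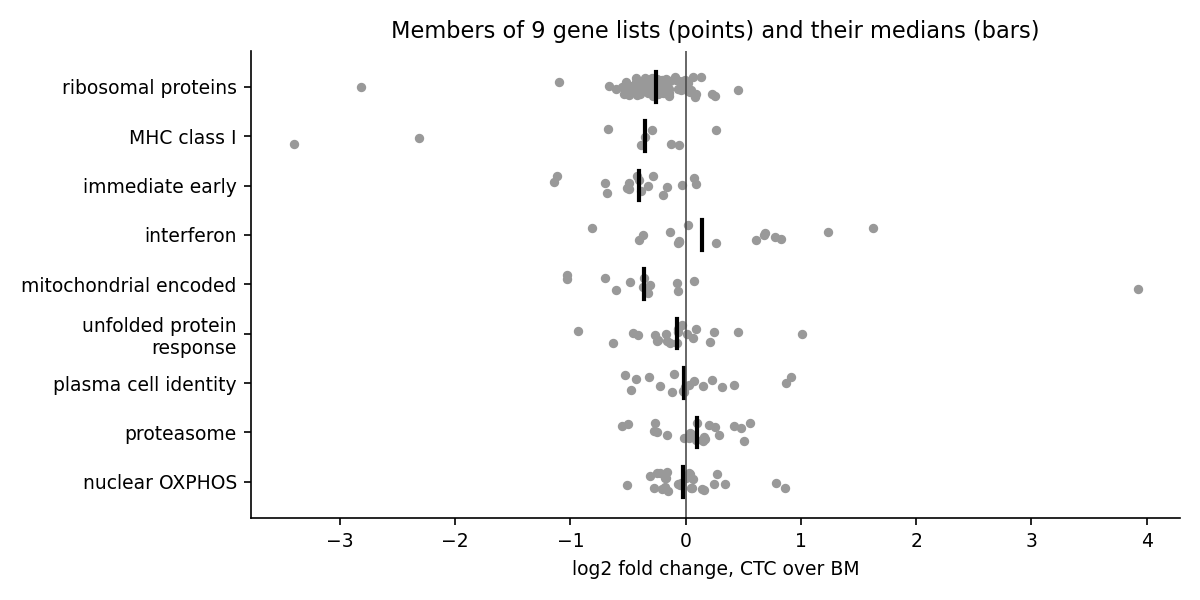
Log2 fold change of CTC over BM for the tested members of 9 gene lists (points) with the median of each list (bar). The medians were −0.26 for ribosomal proteins, −0.35 for class I antigen presentation and −0.40 for immediate early genes, and MT-ND6 is the point at 3.92.

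Interferon-stimulated genes and the mitochondrial genome lay just outside the threshold. Of 16 interferon-stimulated genes, 9 were positive. Those of lowest p were XAF1 (1.63), IFIT1 (1.23), MX1 (0.83) and OAS2 (0.68), each positive in 3 of 3 patients (camera adjusted p = 0.0710, 0.995 with an estimated correlation). Of the 13 protein-coding mitochondrial genes, 11 were negative, with MT-ND3 at −1.03, MT-CO1 at −1.03 and MT-CO2 at −0.70, while MT-ND6 rose (camera adjusted p = 0.0710 for the list). The mitochondrial list turned to the higher side by camera with cells above 25% mitochondrial counts removed (adjusted p = 0.994) and without patient 3 (0.888), and the interferon list passed by camera with immunoglobulin genes left out (0.0265, but 0.987 by fry). MT-ND6 was also the 1 member that passed when adjusted over the list alone. MT-ND3, a complex I subunit like MT-ND6, was lower in 3 of 3 patients, by −1.03 ± 0.10 (SD, n = 3) on the log2 scale.

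The secretory programs of plasma cells had no list past the threshold. In the list of plasma cell identity, 8 of 18 members were positive (adjusted p = 0.976 from camera, as for the values in parentheses below), with IGJ, the joining chain of secreted antibodies, at 0.92, CD27 at 0.87 and SSR4 at −0.47. Of 10 genes in the plasma cell marker list, 5 were positive (0.754). Among 21 genes of the unfolded protein response, 14 were negative (0.636), with the chaperone gene DNAJB9 at −0.93 and HYOU1 at 1.01. Among 22 proteasome subunits, 15 were positive (0.685), with PSMC4 at 0.56 and PSMD11 at −0.55. Among 8 cytosolic heat shock genes, 7 were negative (0.364), with HSP90AB1 at −0.61 and HSPA8 at −0.89. The calls depended on the patients: without patient 2 the plasma cell marker list (camera adjusted p = 0.00607) and the identity list (0.0290) were higher, though not by fry (adjusted p = 0.872 for both). Without patient 3 the heat shock list was lower (0.0171 by camera and 0.0252 by fry).

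Lists of survival, growth and movement were also without a call. Of 9 BCL2 family genes, 8 were negative (adjusted p = 0.158 from camera and 0.112 from fry), with BCL2L11 at −1.001 and BCL2 at −0.71. The BCL2 family passed by camera with cells above 25% mitochondrial counts removed (adjusted p = 0.0478, but 0.109 by fry), and by fry with gene copies summed (0.00849, but 0.185 by camera). Of 14 nucleolar genes that respond to MYC, 10 were negative (0.429), with DKC1 at −0.68 and SRM at 0.58. Of 28 nuclear genes of the respiratory chain, 14 were positive (0.995), with NDUFC2 at 0.87 and SDHC at 0.78; this list was lower without patient 1 (camera adjusted p = 0.0244) and higher without patient 2 (0.0393), though not by fry (0.998 and 0.872). Of 11 hypoxia and glycolysis genes, 4 were positive (0.995), with GAPDH at 0.60 and PDK1 at −0.76. Of 11 genes of the mesenchymal program, 8 were positive (0.754), with ANXA2 at 0.46 and S100A4 at 0.33. Of 17 adhesion and homing genes, 10 were negative (0.925), with ICAM3 at −0.98, S1PR4 at −1.26 and KLF2 at −0.72. Of 11 genes of NF-kappaB signaling, 7 were negative (0.995), with NFKBIE at −0.53 and TNFAIP8 at 0.59. Of 11 targets of myeloma therapies, 6 were negative (0.976), with GPRC5D at 0.56 and PSMB5 at 0.51. No member of these 8 lists passed, whether over all genes or when adjusted over the list alone. The lists of DNA replication (MCM7 at 0.81, PCNA at 0.29), mitosis (STMN1 at 0.88, HMGB2 at −0.67) and class II antigen presentation (HLA-DMA at 0.79, CD74 at −0.14) had fewer than 5 tested genes and were not tested as lists.

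Summed profiles followed the patient more than the compartment. BM and CTC samples of the same patient correlated at 0.816 ± 0.0594 (SD over 3 pairs of samples, Pearson's r across 4249 genes). Samples of the same compartment from different patients correlated at 0.649 ± 0.0508 (6 pairs of samples), close to the 0.664 of samples that shared neither. Without immunoglobulin genes the values were 0.810 and 0.662. Genes are not independent replicates, so no test was made. Over all genes with a count the difference shrank from 0.167 to 0.0673.

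Within each patient, CTC and BM cells lay apart in expression space. A cell had 1.95, 1.70 and 1.83 times the share of neighbours of its own compartment that a lack of structure would give in patients 1, 2 and 3, where 1 means full mixing. The mean was 1.83 ± 0.121 (SD, n = 3). Full separation would give a ratio of about 2.02, as in the simulated cells with shifted genes. Cells on different plates of the same sample also lay apart, with ratios of 1.15 in BM 1, 1.68 in BM 2, 1.48 in BM 3 and 1.74 in CTC 3 (1.51 ± 0.265 SD, n = 4). The difference between both sets of ratios was not tested. CTC and BM cells never shared a plate, so separation by compartment and by plate cannot be told apart.

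**Figure D3:**
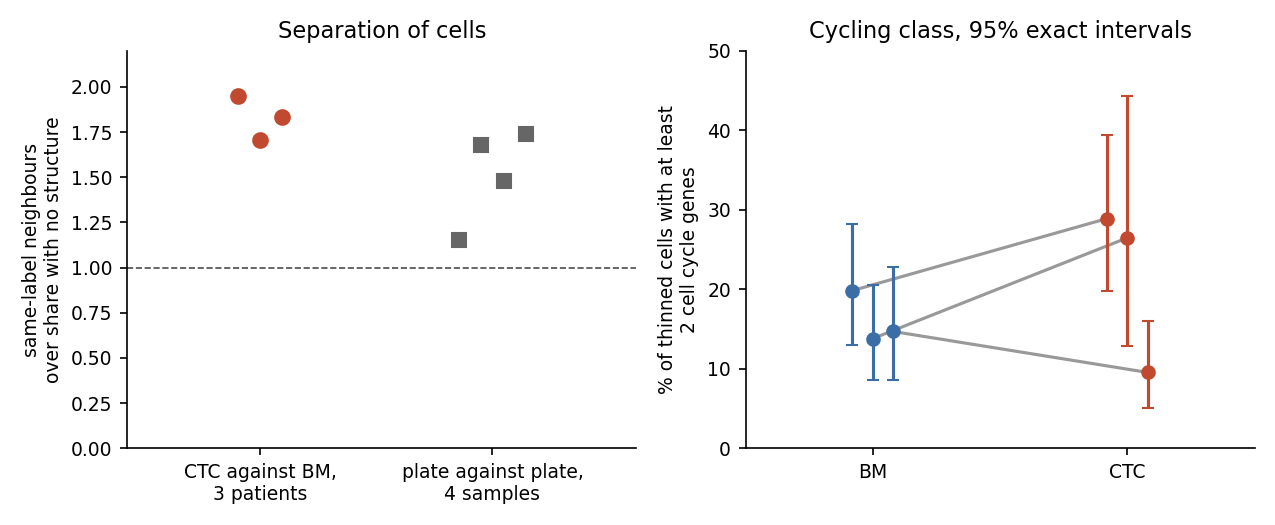
Left, same-label neighbours over the share with no structure (dashed line at 1) for CTC against BM in 3 patients and for plate against plate in 4 samples; right, percentage of thinned cells in the cycling class per sample with 95% exact binomial intervals, lines joining the samples of a patient. The compartment ratios were 1.70 to 1.95 and the plate ratios 1.15 to 1.74, and the cycling share was higher in CTC samples of 2 patients and lower in the remaining patient.

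Cells with transcripts of genes in the cell cycle lists were found in both compartments. The class does not establish that these cells divide: in CTC 2, MKI67 and CENPF were at 0 CPM. TUBB4B alone held 282 of the 374 CPM of the mitosis list in CTC 2, and 112 of 458 in CTC 1. The cycling class held 23 of 116 thinned cells in BM 1 (19.8%, 95% exact binomial interval 13.0 to 28.3), 20 of 145 in BM 2 (13.8%, 8.63 to 20.5) and 16 of 109 in BM 3 (14.7%, 8.63 to 22.7). In CTC samples it held 26 of 90 cells in CTC 1 (28.9%, 19.8 to 39.4), 9 of 34 in CTC 2 (26.5%, 12.9 to 44.4) and 12 of 126 in CTC 3 (9.52%, 5.02 to 16.05). The difference of 5.53 ± 9.43 percentage points (SD, n = 3) had p = 0.5 in the exact sign-flip permutation test and p = 0.4 in the exact permutation of the 6 values, and both were 1 after adjustment. Without thinning the shares were 37.0%, 30.8% and 25.3% in BM and 51.1%, 28.0% and 16.9% in CTC samples. With at least 3 cycle genes asked for, they were 6.90%, 2.07% and 0.917% in BM and 12.2%, 5.88% and 2.38% in CTC samples, higher in 3 of 3 patients. These shares rest on few cells of a single random thinning, with 34 thinned cells in CTC 2. Over 20 repeats of the thinning, with 2 genes asked for, the difference had no fixed sign in any patient. It ran from −3.89 to 12.4 percentage points in patient 1, −1.16 to 14.1 in patient 2 and −14.1 to 0.524 in patient 3. With cells thinned to the median depth, patient 2 turned to the lower side (22.1% in BM and 18.8% in CTC). The class is a range and not a cell type: 301 of the 620 thinned cells had 1 or 2 of its genes, and over 20 repeats of the random thinning the difference averaged 1.45 percentage points, with a range from −3.02 to 6.82. The mean Spearman correlation between cells of a sample was 0.341 ± 0.0168 in BM and 0.337 ± 0.0303 in CTC samples, with a difference of −0.00378 ± 0.0466 (SD, n = 3; exact sign-flip permutation p = 1.00). The patients moved apart, by 0.05002, −0.0304 and −0.0309, and in patient 1 the unthinned values were 0.249 in BM and 0.387 in CTC cells.

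Plasma cell genes were present in nearly every thinned cell. At least 2 of the 10 plasma cell markers were detected in 106 of 116 thinned cells of BM 1, 85 of 90 of CTC 1 and all thinned cells of the other 4 samples. Some kept cells had at least 2 markers of another cell type and more of them than of plasma cells. They numbered 10 in BM 3, 6 in CTC 2, 3 in CTC 3 and 1 in each other sample, and entered the summed counts. In BM 3, 3 of 9 kept wells with T or NK cell genes held at least 2 plasma cell markers. Genes of T cells and of NK cells were each detected, with at least 2 markers, in 7 of 34 thinned cells of CTC 2 (20.6%), and in at most 0.690% and 0.917% of those in the other samples. The summed counts of all kept cells show less of a contrast: NK cell markers were at 432 CPM in BM 3 and 472 in CTC 2, and T cell markers at 214 in CTC 1 and 282 in CTC 2. Erythroid genes were found in 5.88% of CTC 2 and 6.35% of CTC 3 cells, 2.07% of BM 2 cells and 0 cells of the other samples. B cell genes were found in 9.48% of BM 1 cells and in 0.917% to 5.88% elsewhere. Monocyte genes reached at most 2.94%, granulocyte genes 1.38% and platelet genes 0.917% of the cells of a sample. Dendritic, stromal or endothelial, and progenitor markers were found, with at least 2 markers, in 0 thinned cells, from 145 in BM 2 to 34 in CTC 2. Single markers had counts, such as 29.7 CPM of stromal or endothelial markers in BM 1, and how often such a cell would show 2 markers at this depth was not measured. In the summed counts CD79B (−0.23) and MS4A1 (0.07) of the B cell list and S100A8 (0.39) and S100A9 (0.22) of the monocyte list were tested and did not pass, and no gene of the T cell, NK cell, granulocyte, platelet, dendritic, stromal or progenitor lists had enough counts for a test. No share passed the exact sign-flip permutation test (smallest p = 0.5, n = 3).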

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

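The value below was chosen after the data were seen. The 133 wells with fewer than 200 detected genes were left out of the comparisons, except for the alternative with no filter on cells, and mitochondrial transcripts made up 61.7% of their 20396 counts. The value is given because these wells lie outside the reported comparisons and their share was above 0, and there were no control wells to set it against. In the kept cells of the 6 samples the share was 9.19% to 25.1%. Immunoglobulin transcripts made up 9.76% of those counts. The median such well held 62 counts over 33 genes, and 11 of the 133 wells held at least 500 counts. The share was 66.6% in the 77 BM wells and 47.9% in the 56 CTC wells. No explanation was tested.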

How the results depend on the processing

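The alternatives with 1 plate per sample, with gene copies summed and with wells rich in haemoglobin removed, the mitochondrial filter for lists, and leaving out patients in the comparison of patient with compartment were chosen after the data were seen, and the others before. Across 572 values under alternatives, 505 stayed on their side of the threshold with the same sign or within the spread between replicates. Named and panel genes made up 383 of them and 352 stayed, mostly genes that had no call to lose, since only MT-ND6 had passed. For the 3 called lists, 20 of 36 values stayed, 15 lost the call and 1 changed sign. The number of genes past the threshold (1) became 2 with DESeq2 and 2 with cells of other types removed, 5 with no filter on low counts, and 0 with no patient block, with at least 20 counts in 3 samples, with equal cell numbers and with gene copies summed. At unadjusted p under 0.05 the last 4 settings gave 33, 41, 54 and 75 genes by edgeR. It ran from 0 to 38 when a patient was left out and from 0 to 2 over the 16 choices of 1 plate per sample (0 in 13). In the other 11 settings the count was 1. MT-ND6 stayed positive (3.11 to 4.17 on the log2 scale) and past the threshold in 15 of 21 settings, with adjusted p from 1.00e-09 to 0.999. Over the 16 plate choices it passed in 1 and ran from 3.05 to 4.57. The number of lists (3) became 0 with an estimated correlation or fry, 1 with thinned cells, 1 to 4 with 1 plate per sample, and 2 to 5 when a patient was left out; it was 2 with no patient block, 4 without immunoglobulin genes and 2 without wells rich in haemoglobin. Ribosomal proteins were lower and past the threshold in 16 of 16 plate choices (camera adjusted p up to 0.0163), class I genes in 8 and immediate early genes in 4. Every choice held the same single plates of CTC 1 and CTC 2, so an effect of those plates was not examined. The CTC 2 plate had the lowest ribosomal share (6.24%), and the ribosomal call was lost without patient 2. The immediate early list had adjusted p from 0.00572 to 0.895 when a patient was left out, with the sign turned without patient 1. The mixing ratio was 1.62 with 30 neighbours, and the gap between same-patient and same-compartment correlations was 0.0673 over all genes with a count and 0.155 to 0.281 when a patient was left out. Panel genes near 0 changed sign: TNFRSF17 to −0.032 and CD38 to −0.070 without the block, CD38 to −0.0088 with no filter, TNFRSF17 to −0.0041, LGALS1 to −0.084 and SDC1 to 0.051 with thinned cells. With a patient left out, CD44 ran from −0.56 to 0.047, CXCR4 from −0.28 to 0.69, TNFRSF17 from −0.29 to 0.52, LGALS1 from −0.20 to 0.68, SDC1 from −0.64 to 0.49 and CD38 from −0.18 to 0.42. The cause was not tested for any of these, except that fewer samples or genes entered some of them. Simulated 4-fold changes were found in 24% of genes, and whether depth, the number of pairs or the dispersion set this limit was not tested.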

Other observations

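Some wells of CTC 2 held transcripts of other blood cells beside those of plasma cells. Whether both came from the same cell was not tested. In 13 of its 82 wells at least 2 genes of the T cell and NK cell lists were detected, most often GNLY (8 wells), CD2, NKG7 and TRAC (7 wells each). Immunoglobulin transcripts made up over 10% of the counts in 11 of these 13 wells. The CTC wells left out by the cell filter held 14.2%, so a share over 10% does not by itself show a plasma cell in the well. The 11 wells had a median immunoglobulin share of 28.2%, with 3184 counts and 1206 genes, while the wells of CTC 2 without such genes had 32.7%, 1731 counts and 701 genes. Detection of 2 genes in counts that were not thinned favours deep wells. The higher counts and genes are thus partly given by the choice of wells and do not show more than 1 cell per well. In BM 3, 2 of 9 wells with such genes were over 10% immunoglobulin, in BM 1 it was 5 of 6, in BM 2 it was 1 of 1, and CTC 1 and CTC 3 had 0 such wells.

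Of the tests in the following paragraphs, that of the direction of gene copies over all samples was written down before its result was seen, and the others, its division by sample included, were chosen after the data were seen. For MT-ND6, the tables argue against counts moved from its annotated copies, since MT-ND6 summed with its 20 copies still changed by 3.10 ± 0.67 (log2, SD over 3 pairs), and against more mitochondrial RNA in circulating cells, since the other 12 protein-coding mitochondrial genes, summed, changed by −0.36 ± 0.16. A library effect of single plates stays open: MT-ND6 differed 9.20-fold between the plates of CTC 3, it was found in 87 of 92, 73 of 82 and 66 of 81 cells on the 3 plates where it was high, and both plates of each BM sample were low. The lowest CTC plate (79.9 CPM) was near the highest BM plate (77.9). A difference between the compartments stays open as well and may act beside the plate.

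For haemoglobin, 98.0% of all counts lay in 10 wells. Free RNA spread over all wells is argued against as the main source on the CTC 2 plate and the first CTC 3 plate. There 3 and 6 wells held 100% and 99.5% of the haemoglobin counts. On the first CTC 3 plate 12 other wells of 73 held fewer than 10 counts each, so a low spread beside the rich wells stays open. Free RNA also stays open in CTC 1, where the 27 counts lay in 16 of 92 wells and 0 wells had at least 10. Expression by circulating tumor cells in general is argued against by the 2.74% of 328 CTC wells with at least 10 haemoglobin counts. Red cell material in single wells stays open as a candidate source: 3 of 9 such CTC wells held any of the 5 genes of the erythroid list that do not encode haemoglobin, against 2 of 319 other CTC wells (Fisher's exact test, two-sided p = 1.40e-04). This test takes wells as units and does not cover differences between patients or plates. The 9 wells also held 30.9% immunoglobulin transcripts, close to the 32.8% of the other CTC wells, so they held plasma cell RNA too. The haemoglobins reached 12.8% of their counts.

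Between the plates of a sample, 18 genes in BM 1, 44 in BM 2, 19 in BM 3 and 32 in CTC 3 lay at least 10-fold apart (exact binomial test, adjusted p under 0.05, genes with at least 20 counts), among them HLA-B and HSPA8 in BM 3 and the haemoglobin genes in CTC 3. Of these 113 cases 53 had a copy by symbol and 60 had none; the share with a copy was 55.6%, 47.7%, 36.8% and 46.9% in BM 1, BM 2, BM 3 and CTC 3, against 21.8%, 24.6%, 25.2% and 27.4% of the other genes (Fisher's exact test, adjusted p = 0.00381, 0.00381, 0.287 and 0.0348). Variation between cells is argued against for most of the set, since 20 random divisions of the same wells gave at most 5 such genes in a sample, 15.6% of the count between plates at the highest. Such variation stays open for the haemoglobin genes of CTC 3, since 6 wells of the first plate held 99.5% of that plate's haemoglobin counts. In BM 2 the copies were higher on the plate on which the gene was low in 1 of 18 families (5.56%, exact binomial p = 1.45e-04). This cannot decide whether counts moved between copies, since the BM 2 plates differed in composition. Ribosomal protein genes held 7.62% of counts on the first and 10.3% on the second. With copies summed, 0 of the 21 BM 2 genes with a copy stayed 10-fold apart, which a sum with an abundant member can also give. Moved counts stay open in BM 2, and also in BM 1 (7 of 8, exact binomial p = 0.0703), BM 3 (1 of 4, p = 0.625) and CTC 3 (4 of 12, p = 0.388). The 31.0% of all 42 families (exact binomial p = 0.0195) became 50% without BM 2, and no biological explanation was tested.

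With 6 samples there are 10 ways to form groups of 3, too few for a share under 0.05. The real division gave 1 gene and the highest other 5, and 4 of the 10 gave at least 1. For the lists, the real division gave 3 and the highest other 7, and 8 of the 10 gave at least 3. The 7 came from divisions that part the samples of only 1 patient. With the patient block, such divisions estimate the change from that patient alone and are not like the real one. They also come in mirrored pairs that give the same numbers of genes and lists, so the counts out of 10 hold each such fit more than once. Among the 4 divisions that part all 3 patients' samples, the real one included, the number of genes was 1 for the real one, 5 when CTC 3 and BM 3 changed places and 0 for the others. The number of lists in these 4 was 3 for the real one, 5 when CTC 3 and BM 3 changed places, 6 when CTC 2 and BM 2 did and 3 for the last. At unadjusted p under 0.05 the real one gave the fewest genes by edgeR, 78. The others gave 391, 126 and 142 in the same order.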
